A study of Mus musculus with 5 samples.

How the data were processed

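The data were 5 dual-colour arrays of mouse retina, each with wild-type RNA in channel 1 and Rb-mutant RNA in channel 2, per the labels. Per the labels, spots were quantified with GenePix Pro 4.1.1.29 from scans at 635 and 532 nm, with local background subtraction and no normalization. The filter behind the empty cells, the dye of each RNA and any dye swap are not given in the sources used here. The values used are the log2 ratios deposited by the authors, with the log scale read from the values themselves. Their array medians were -0.755, -0.025, -0.715, -0.0575 and -0.742 on arrays 1 to 5, so the deposited ratios were not centred. Per the labels, the scanner software formed ratios as 635 over 532 nm. Whether the deposited values keep that order is not stated, and with no dye named for either RNA the direction remains unknown. The factors for the ratio of medians in the labels were 1.38, 1.01, 1.60, 0.913 and 1.87 and were not applied. Other factors in the labels, among them an Arabidopsis factor that was highest on array 2, were not applied either.

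Cells at 16.61, the log2 of 100000 and taken as a filler for a ratio with a zero denominator, numbered 130, 141, 134, 124 and 106 on arrays 1 to 5 and were treated as missing. This was decided after the values were seen, and keeping them is among the alternatives. Usable ratios then covered 73.2%, 71.8%, 75.9%, 73.2% and 75.1% of spots. The number of arrays and the spread between them, not a depth, limit the precision. No intensity was used, so dim spots could not be told from bright ones by signal over background. The 192 spots of the control ACTB were left out of all tests. Their medians after centring were 1.09, -2.10, 0.71, -0.30 and 0.05 log2 on arrays 1 to 5. Array 2 lay lowest, and whether this bears on its other ratios was not tested.

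Each array was centred on its median. Because spots missing on some arrays had other ratios than spots measured on all, the median of all genes in the gene table was -0.39, 0.01, -0.43, 0.13 and -0.27 on arrays 1 to 5, and gene lists are given relative to it. Gene names came from the platform annotation, with gene identifiers matched to the RefSeq table of assembly GRCm38.p6, in which 7663 spots had an entry. A single gene symbol was listed for 7722 spots, several for 353 and none for 9061. No spot with several symbols was named. The genes named for their smallest p are given by the chosen probe, with the other probes of several of them beside it.

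Probes measured on at least 4 of the 5 arrays were tested against a ratio of 0 with an intercept in limma 3.58.1 (R 4.3.3), lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The gene table held the mean of each gene's probes measured on all 5 arrays, 3739 genes. Gene lists were tested on it with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured genes, with camera at an estimated correlation and fry beside it. The list value given with an alternative is the mean of its genes minus the mean of all genes. Percentiles of list medians within an array came from 10000 random lists of the same size, not matched on expression. The 27 lists, with 767 entries, were fixed before the data were examined, as were the samples, tests and the first set of alternatives. Of these, 18 had enough genes. The lists of bipolar cells (4 genes measured), myelin and astrocytes (2), interferon and antigen presentation (2), lens (1), vessels (1), microglia and macrophages (1), fibroblasts and matrix (1), pigment epithelium (0) and blood (0) were too small to test.

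The genes named were chosen by a rule fixed in advance. It took Rb1, the 10 probes with the largest positive and the 10 with the largest negative mean past the threshold, up to 4 members of each list with the smallest limma p, and Nrl, Crx, Ccne1, E2f1, Mcm6, Pcna and Cdkn1b wherever measured. A further gene of the rule is not reported here. Since no probe passed, the places were filled by the smallest limma p among single-symbol probes of the same sign on all 5 arrays. Pde6g, Esrrb, Guca1b, Gucy2f and Arr3 fall outside the rule and were chosen after their values were seen. Rb1 was also tested with an exact two-sided sign-flip permutation test over the 5 arrays.

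The probe test was tested on simulated data with 10036 probes, 200 of them changed. At the real spread 0%, 0% and 84.5% were recovered at 1, 2 and 4 log2 units, with 17 unchanged probes called at 4. With the spread scaled down by a factor of 10 98%, 100% and 99.5% were recovered. The list test called a list shifted by -1 in 50 of 50 draws, with 0.02 unshifted lists called per draw on average. Genes were drawn independently there. In the data the estimated correlation between genes was 0.68 for replication, 0.33 for mitosis, 0.50 for rods and 0.14 for Rb and E2F. The simulation therefore does not test the preset correlation of 0.01 on these lists. Alternatives tried were other centring and scaling of arrays, quantile normalization, other rules for missing values and zeros, array weights, robust fitting, an unmoderated test, other thresholds, the scan group, all sign patterns, genes in place of probes, all probes in place of genes, and each array left out in turn.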

Results

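Gene expression in the retina of mice lacking functional Rb, the retinoblastoma tumour suppressor that restrains entry into S phase, was set against that of wild-type mice on 5 dual-colour spotted arrays. The series title names retinal explants, that is, retina kept in organ culture. All 5 arrays carried the same labels, with wild-type total RNA in channel 1 and mutant RNA in channel 2. They form a single group of 5 replicates, numbered here as arrays 1 to 5 in order of deposition. Each array held 17328 spots, of which 12683, 12444, 13145, 12682 and 13010 gave a usable log2 ratio on arrays 1 to 5. The labels give the scanner software's ratio as 635 over 532 nm, and do not say which dye marked which RNA or whether the deposited values keep that order. Positive and negative ratios are therefore given as deposited, and neither is assigned to the mutant. The labels also do not say whether the arrays came from separate animals or cultures. The p-values of probes, genes and fry therefore measure only the spread between these arrays, which may be technical. Camera at the preset correlation of 0.01 sets a list's genes against other genes and takes them as nearly independent. Its p-values therefore do not measure how well a list repeats between arrays. The number of arrays and the spread between them limit the precision.

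The comparison asks which genes differ between Rb-mutant and wild-type retina. Known work on this mutation concerns proliferation of retinal progenitors and development of rods, the photoreceptors of dim light. Rb1 itself, the targeted gene, was measured on all 5 arrays by a single probe, with log2 ratios of -0.07, 0.20, -0.23, 0.04 and -0.08 on arrays 1 to 5. Its mean was -0.03 ± 0.16 (SD, n = 5), with an exact two-sided sign-flip permutation p of 0.688, where 0.063 is the smallest p that 5 arrays allow. The sign of this mean turned positive, to 0.14, when arrays were centred on the probes measured on all of them. The other Rb1 probe, measured on 4 arrays, gave 0.95, 2.06, -1.33 and 1.72 on arrays 1, 2, 3 and 5. The allele is not given here, and whether it alters the RNA that either probe detects is not known, so neither checks the labels.

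Genes of the rod photoreceptor lay far below all genes on arrays 1 and 3, less so on array 4, and not on arrays 2 and 5. The median of the 18 measured rod genes minus the median of all 3739 genes was -2.87, 0.09, -2.90, -0.42 and 0.38 log2 on arrays 1 to 5, a mean of -1.15 ± 1.61 (SD, n = 5). All 18 rod genes lay below the median of all genes on array 1, 14 on array 3 and 14 on array 4, against 8 on array 2 and 5 on array 5. The arrays differed in spread, so log2 sizes are not directly comparable between them. The scaled median absolute deviation of probes measured on all 5 was 0.97, 0.48, 0.97, 0.58 and 0.63 on arrays 1 to 5. Among random lists of the same size the rod list lay at percentiles 0, 79.1, 0, 0.25 and 98.75. Pde6g, the inhibitory subunit of the rod phosphodiesterase, had log2 ratios of -5.80 and -8.18 on arrays 1 and 3 and 0.08, -0.27 and -0.83 on arrays 2, 4 and 5. Rom1, a protein of the outer segment disc rim, had -4.72 and -4.86 on arrays 1 and 3 and -0.03, -0.40 and -0.21 on arrays 2, 4 and 5. Nrl, the transcription factor that specifies rods, had -3.45 and -3.92 on arrays 1 and 3 and 0.20, 0.23 and -0.28 on arrays 2, 4 and 5.

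The rod genes with the smallest p over the 5 arrays were Gnat1, the rod transducin alpha subunit, with a mean log2 ratio of -1.56 ± 1.39, Samd11 with -2.51 ± 2.43, Pdc, which encodes phosducin, with -1.98 ± 2.38, and Rom1 with -2.04 ± 2.51 (SD, n = 5 each). The size on single arrays varied between rod genes. Gnat1 had -3.27, -1.21, -0.77, -2.65 and 0.12 on arrays 1 to 5. Esrrb, Guca1b and Gucy2f, chosen after their values were seen, were also lower on array 4, at -5.37, -1.98 and -2.34, than on array 3, at -1.13, 0.80 and 0.27. They had -1.75, -1.82 and -0.70 on array 2, lower than on array 1, at -0.97, -0.49 and -0.44. Rod genes with a log2 ratio under -1 numbered 14, 4, 13, 4 and 0 on arrays 1 to 5. Crx, a transcription factor shared by rods and cones, did not share the large negative ratios, with -1.16, 0.62, -0.28, 0.79 and 0.76 on arrays 1 to 5. Its other probe, on 4 arrays, gave 0.16, -2.84, -1.02 and -1.64 on arrays 1, 2, 3 and 5. The second Nrl probe was measured only on arrays 2, 4 and 5, at 0.35, 0.11 and 2.41. As a group, the rod genes passed the limma camera test on the negative side (adjusted p = 0.00593), and the call was lost with an estimated correlation (adjusted p = 0.935). None of the 18 passed on its own, 0 over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. Without array 1 the rod list was -0.73 from all genes with an adjusted p of 0.152, and without array 3 it was -0.72 with an adjusted p of 0.0303. With both arrays left out, an alternative added after seeing the data, it was 0.07 with an adjusted p of 0.98.

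Cone photoreceptor genes, 7 measured, followed the rod genes on arrays 1 and 3 without passing the test (adjusted p = 0.424). Their median minus that of all genes was -0.94, 0.29, -1.13, 0.33 and -0.16 on arrays 1 to 5. On each of arrays 1 and 3, 5 of the 7 lay below the median of all genes and 2 above. Arr3 was above it on both, at 0.94 and -0.01. Opn1sw, the short-wavelength cone opsin, had log2 ratios of -4.51 and -4.18 on arrays 1 and 3 and 0.41, 0.73 and 0.33 on arrays 2, 4 and 5. Gnb3, the cone transducin beta subunit, had a mean of -0.89 ± 0.78, Opn1mw, the medium-wavelength opsin, -0.78 ± 0.83, and Thrb, a thyroid hormone receptor that patterns cone opsins, -0.47 ± 0.78 (SD, n = 5).

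Genes of DNA replication and of mitosis lay on the positive side, most clearly on the same arrays 1 and 3 on which the rod genes were far below all genes. The median of the 19 measured replication and S-phase genes minus that of all genes was 1.67, -0.08, 1.85, 0.54 and 0.05 log2 on arrays 1 to 5, a mean of 0.81 ± 0.90 (SD, n = 5). The 25 genes of G2 and mitosis gave 1.58, 0.07, 1.57, 0.30 and 0.06, a mean of 0.71 ± 0.79 (SD, n = 5). All 19 replication genes lay above the median of all genes on arrays 1 and 3, and 17 did on array 4, against 6 on array 2 and 11 on array 5. Among random lists of the same size the replication list lay at percentiles 100, 20.1, 100, 99.99 and 62.85 on arrays 1 to 5. Pcna, the sliding clamp of DNA polymerase, had log2 ratios of 1.21, -0.07, 1.88, 1.20 and 0.34 on arrays 1 to 5. Smc2, a condensin subunit that compacts mitotic chromosomes, had 2.99, 0.38, 2.74, 2.99 and 1.07.

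Among replication genes, Rpa2, a subunit of the single-strand binding protein, had log2 ratios of 2.10, 0.01, 2.95, 1.09 and 1.34 on arrays 1 to 5. The DNA ligase Lig1 had a mean of 1.14 ± 1.08 and the histone chaperone Nasp 0.89 ± 0.88 (SD, n = 5 each). Among mitotic genes, Mad2l1, a spindle checkpoint protein, had 1.47 ± 0.88, the kinase Nek2 1.21 ± 1.18 and the mitotic kinase Cdk1 1.45 ± 1.64 (SD, n = 5). On single arrays Cdk1 had 3.78, -0.085, 2.36, 1.17 and 0.007 on arrays 1 to 5. The probes of some genes disagreed. Mcm6, part of the replicative helicase, had 2.98, -0.09, 3.16, 0.72 and 0.29 on one probe and -0.36, -0.44, -0.32, 0.45 and 0.55 on the other. Ccne1, the cyclin of S-phase entry, had 2.45, 0.09, 2.11, 1.48 and -0.48 on one probe and 0.07, -0.21, -0.19, -0.14 and -0.66 on the other. Both lists passed camera on the positive side (adjusted p = 1.14e-10 for replication and 4.72e-10 for mitosis), and both calls were lost with an estimated correlation (adjusted p = 0.653 for each). None of their genes passed over all genes. Adjusted over the list alone, 0 replication genes and 2 mitotic genes passed, Smc2 and Mad2l1. Both calls held without each array in turn and were lost with arrays 1 and 3 both left out, at 0.27 and 0.30 with an adjusted p of 0.209 for each.

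The Rb and E2F family, the pocket proteins and the transcription factors they bind, was the remaining list that passed on the positive side. The median of its 7 measured genes minus that of all genes was 0.72, 0.05, 0.66, 0.10 and 0.28 on arrays 1 to 5, above 0 on all 5 arrays. On arrays 2, 4 and 5 it lay only at percentiles 62.4, 65.3 and 86.1 of random lists. On arrays 2 and 4, 4 of the 7 genes lay above the median of all genes. E2f1, the E2F that drives S-phase genes, had log2 ratios of 1.92, 0.45, 1.92, 0.23 and 0.88, a mean of 1.08 ± 0.80 (SD, n = 5). Rbl1, which encodes the Rb relative p107, had a mean of 0.87 ± 0.69 and Tfdp1, the dimerisation partner of E2F proteins, 0.37 ± 0.52, while E2f6 had -0.07 ± 0.35 (SD, n = 5 each). The list passed camera (adjusted p = 0.0183), and the call was lost with an estimated correlation (adjusted p = 0.653), without array 1 (0.37, adjusted p = 0.152), without array 3 (0.40, adjusted p = 0.0969) and without both (0.17, adjusted p = 0.883). None of the 7 passed over all genes, and 0 passed adjusted over the list alone.

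**Figure D1:**
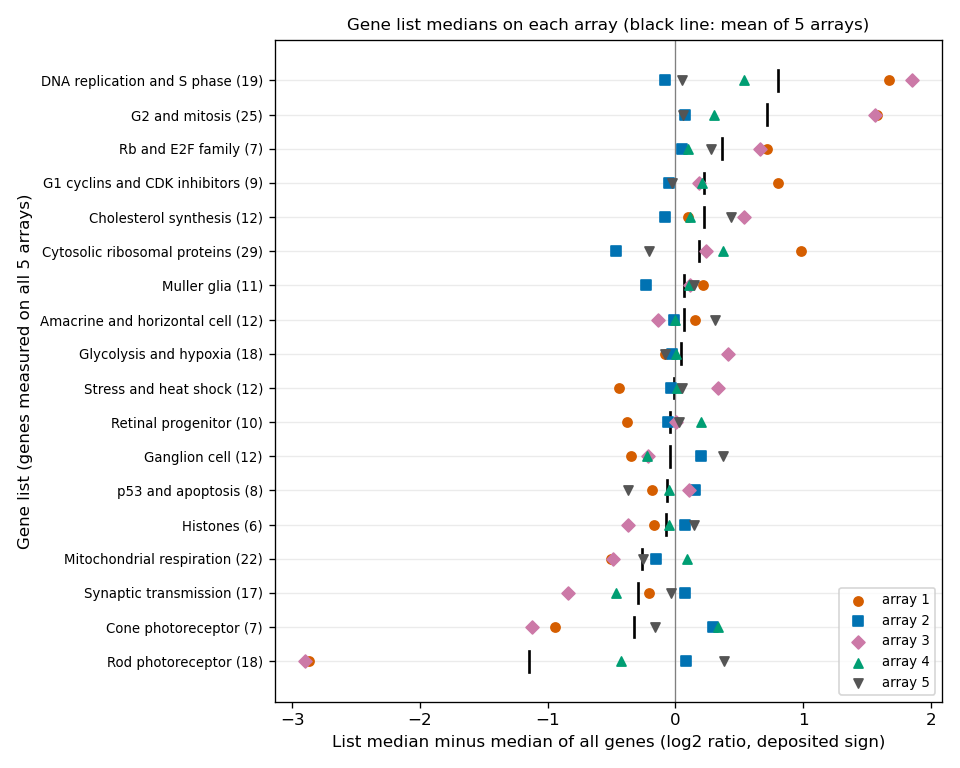
Median log2 ratio of each gene list minus the median of all 3739 genes, with a point for each of the 5 arrays, a black line for the mean of the 5 arrays, and the number of measured genes beside each list name. The rod list lay at -2.87 and -2.90 on arrays 1 and 3, and the replication list at 1.67 and 1.85 on the same arrays.

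The cyclins and inhibitors of G1 did not pass as a list of 9 genes (adjusted p = 0.0972). Cdkn1a, the p53-responsive inhibitor p21, had log2 ratios of 3.05, -0.06, 2.99, 0.64 and -0.76 on arrays 1 to 5. Ccnd2, a D-type cyclin, had a mean of 0.84 ± 0.67, Cdkn1c 0.76 ± 1.17 and Ccnd1 -0.49 ± 0.93 (SD, n = 5 each). No spot was listed for Cdkn1b. Mitochondrial respiration, with 22 genes, missed the threshold on the negative side (adjusted p = 0.0514), with Cox4i1 of cytochrome oxidase at a mean of -0.79 ± 0.55 and Atp5b of the ATP synthase at -0.97 ± 0.87 (SD, n = 5 each). This list lay close to the threshold and passed in 8 of 20 alternatives, with an adjusted p of 0.00472 without array 4 and 0.341 without array 1, at -0.30 and -0.10 from all genes. The 17 synaptic genes gave an adjusted p of 0.155, with Cplx2, a complexin of vesicle release, at -1.09 ± 0.66 and Syp, synaptophysin, at -1.04 ± 1.04, while the glutamate receptor subunit Grin2b was at 0.98 ± 0.67 (SD, n = 5 each). The 29 ribosomal protein genes (adjusted p = 0.139) moved as a block within arrays and not in a shared direction, with a median minus all genes of 0.98, -0.46, 0.24, 0.37 and -0.21 on arrays 1 to 5. Leaving out a single array also brought other lists past the threshold, mitochondrial respiration (adjusted p = 0.0375), synaptic genes (0.0359) and ribosomal proteins (0.011) without array 2, and G1 genes (0.0391) and ribosomal proteins (0.00892) without array 5. Of the 18 lists tested, 4 passed camera, 0 passed with an estimated correlation and 0 passed limma's fry (smallest adjusted p = 0.283).

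**Figure D2:**
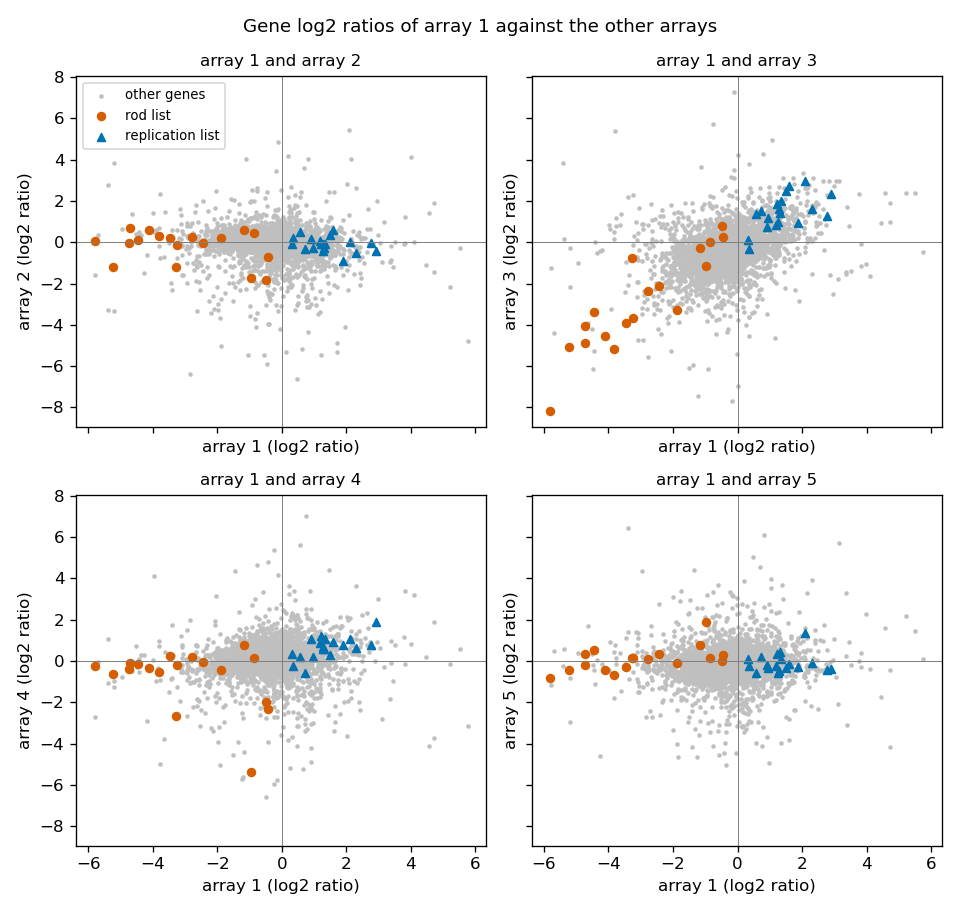
Log2 ratio of each of 3739 genes on array 1 (horizontal axis) against array 2, 3, 4 or 5 (vertical axis, a panel each), with the 18 rod genes as orange circles, the 19 replication genes as blue triangles and other genes in grey. Pde6g, at -5.80 on array 1, lay at -8.18 on array 3 and at 0.08 on array 2.

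No single probe passed. Of 10036 probes tested with limma, 0 had an adjusted p under 0.05, 0 with a positive and 0 with a negative ratio, and the smallest adjusted p was 0.26. The unmoderated per-probe test also gave 0. At an unadjusted p under 0.05 there were 1146 probes, 554 positive and 592 negative, where chance gives 501.8. The split differed by annotation, with 195 positive and 360 negative among probes with a single gene symbol and 359 and 232 among the rest. Of the 3739 genes, 541 had an unadjusted p under 0.05, 123 positive and 418 negative, and 0 passed after adjustment. These genes were tested against 0 while the median of all gene means was -0.22, an offset that enters this split. Of the 6753 probes measured on all 5 arrays, 1030 (15.3%) had the same sign on every array, where independent arrays with the same shares of positive and negative probes would give 7.1%. If the dyes were not swapped, a dye effect on single spots would also give shared signs. Such an effect could not be told apart from the mutation. In simulated data with the spread of these arrays, 0% of 200 probes changed by 1 or by 2 log2 units were recovered, and 84.5% of those changed by 4 were.

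The 10 named probes with the smallest p among those positive on all 5 arrays did not pass (adjusted p from 0.26 to 0.409), and neither did the 10 negative ones. The positive ones were Tpp1, Mbd2, Cecr2, Plekhj1, Smc2, Cdc25a, Kdm5b, Arhgef33, Mad2l1 and Klc1, with means from 1.00 to 2.85 log2. Tpp1, a lysosomal peptidase, had a mean log2 ratio of 2.06 ± 0.72, Mbd2, which binds methylated DNA, 2.16 ± 1.09, and Cdc25a, a phosphatase that activates cyclin-dependent kinases, 1.14 ± 0.51 (SD, n = 5 each). Other probes of these genes went against the chosen ones. The other Tpp1 probe was negative on all 5 arrays with a mean of -0.68, the other Mbd2 probe, on 4 arrays, had a mean of -1.57, and the other Cdc25a probes had means of -0.16 and 0.04. The chosen Kdm5b probe had a mean of 2.85, and the other 3 Kdm5b probes had means of -0.29, -0.87 and 1.06. The negative ones were Tmem109, Senp2, Nek7, Shc2, Zbtb5, Cyth1, Uck2, Shld1, Socs7 and Vat1l, with means from -2.93 to -1.24. Tmem109 had -1.58 ± 0.42, Senp2, a SUMO protease, -1.77 ± 0.74, and the kinase Nek7 -2.93 ± 1.56 (SD, n = 5 each). The other probe of Tmem109 had a mean of -0.43, that of Senp2, on 4 arrays, -0.68, and that of Cyth1 -0.40 against -1.68 for the chosen one. Over the 12 of these 20 genes with another measured probe, 8 of 17 other probes had a mean of the same sign as the chosen probe and 9 of the other sign.

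The arrays resembled each other weakly. Across probes, which are not independent replicates, the Pearson correlation of log2 ratios had a median of 0.117 over the 10 pairs of arrays and ran from 0.0215 to 0.331, highest for arrays 1 and 3. Arrays 2 and 4 came next at 0.274, and arrays 1 and 2 were lowest. No pair lay below 0 by this measure, and arrays 1 and 2 lay at -0.0483 by Spearman correlation. On the 6753 probes measured on all 5 arrays, arrays 1 and 2 lay at -0.0605 by Pearson and -0.158 by Spearman correlation, and arrays 2 and 3 at -0.00158 and -0.0197. No array's sign was turned. Arrays 1, 2 and 3 were scanned at the same focus position and arrays 4 and 5 at another. Within the first scan group alone the rod list was -1.61 from all genes and the replication list 1.28, and within the second 0.04 and 0.35. The arrays of a group differed. By list medians, array 2 of the first group had 0.09 for rods and -0.08 for replication. Array 4 of the second group had -0.42 and 0.54.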

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

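Chosen only after the result was seen were the tests of an unturned dye swap, of different RNA and of the sign patterns. Of 87 results checked for a single array far from the other 4, 4 stood out, and chance alone would give 4.35. The Muller glia list lay at -0.23 relative to all genes on array 2, against 0.10 to 0.21 on the others. The glycolysis and hypoxia list lay at 0.41 on array 3, against -0.08 to 0.00 on the others. Tpp1 had a log2 ratio of 3.33 on array 2, against 1.58 to 1.89 on the others. Cyth1 had -3.23 on array 1, against -1.53 to -0.89 on the others.

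The rod list lay at -2.87 and -2.90 relative to all genes on arrays 1 and 3, beyond any of 10000 random lists. If noise of spots that are dim on every array were the source, the pattern would weaken among genes that vary little elsewhere. Among 2311 genes with an SD under 0.5 over arrays 2, 4 and 5, 12 of the 18 rod genes remained. They lay at -2.86 and -3.01 on arrays 1 and 3. This filter chose rod genes that were steady on arrays 2, 4 and 5, and no intensity was used to check that they were bright. It therefore cannot exclude dim spots, and noise of arrays 1 and 3 alone was not tested. An unturned dye swap of an effect as large as on arrays 1 and 3 would put the rod list far above all genes on arrays 2, 4 and 5. The highest value there was 0.38. These values had been seen before the check was set, so its outcome was already known and it decides nothing. An unturned swap of a single array, or with a smaller effect, was not tested. Different RNA on arrays 1 and 3, such as another age or culture, may account for the pattern and cannot be told apart from the mutation, since the labels give 1 source text for all 5 arrays. A response to the mutation that only some arrays show also stays open and was not tested.

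The replication list lay at 1.67 and 1.85 relative to all genes on the same arrays. A lower share of rods alone, in the RNA that forms the numerator of the ratios, would raise the markers of other cell types alike. Which RNA that is remains unknown. The replication genes lay above the 11 Muller glia genes by 1.46 on array 1 (permutation p = 6e-05) and 1.74 on array 3 (permutation p = 1e-05, the smallest that 100000 permutations give), across genes, which are not independent. Muller glia genes themselves differed, with Rlbp1 at -1.33 and -1.14 and Sox9 at 1.14 and 1.18 on arrays 1 and 3. Against this single list, the differences argue only against a lower share of rods that raised all other cell types alike. Whether different RNA on these arrays was the source stays open.

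More probes had an unadjusted p under 0.05 (1146) than chance gives (501.8). Centring each array as a whole could add such probes, because probes measured on all 5 arrays and probes measured on 4 had different medians. With each of these classes centred on its own median there were 1233, 699 positive and 534 negative, and 0 past the adjusted threshold. Of the 16 sign patterns of the 5 arrays, 1 gave as many probes, the real one, and the highest other, with arrays 2 and 4 turned, gave 753. So few patterns cannot give a share under 0.05. Neither check bears on a dye effect on single spots, which was not tested.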

How the results depend on the processing

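Chosen after seeing the data were the alternatives that keep filler cells, centre blocks of spots, centre on probes measured on all 5 arrays, average a gene over whichever probes an array measured, and leave out arrays 1 and 3 together. The count of probes past the threshold stayed at 0 in every alternative run, and the correlation between arrays moved by less than its spread. Simulated changes of 1 and 2 log2 units were not recovered, so a count of 0 says nothing of stability. Over the alternatives of 9 gene lists, the 4 that passed and those of G1, cones, mitochondrial respiration, ribosomal proteins and synapses (the other 9 lists were not followed singly), 137 kept direction and side of the threshold, 19 came to pass, 17 no longer passed and 7 reversed. Those that came to pass were 8 of 20 alternatives for mitochondrial respiration, 5 for ribosomal proteins, 3 for G1 and 3 for synapses. The rod list is 2 of the 7 reversals, and there it also no longer passed. The number of lists past the threshold, 4, became 0 with an estimated correlation, 0 with fry, 7 on arrays 1 to 3 alone (same focus position), 0 on arrays 4 and 5 alone, and 0 with arrays 1 and 3 both left out. It ran from 2 to 7 when each array was left out, 2 without array 1 and 7 without array 2. On arrays 4 and 5 alone the rod list reversed to 0.0389, the cone list to 0.315 and mitochondrial respiration to 0.0902. With arrays 1 and 3 both left out, rods reversed to 0.0708, cones to 0.167, mitochondrial respiration to 0.016 and ribosomal proteins to -0.0471. Fewer arrays entered these fits, and each value is a mean over the arrays kept and the genes measured on all of them. By its median the rod list lay at -2.87 and -2.90 on arrays 1 and 3, so leaving both out removed most of its negative value. It stayed at -1.192, -1.275 and -1.438 without array 2, 4 or 5. Why arrays 1 and 3 stood apart stays open. The Rb1 ratio reversed to 0.0125 with quantile normalization, 0.139 centred on probes on all 5 arrays, and 0.85 on its probe on 4 arrays, and ran from -0.0836 to 0.0241 with each array left out. Centring on probes on all 5 arrays shifts every ratio, since their medians under the main centring were -0.318, -0.016, -0.361, 0.0815 and -0.218. The 0.85 comes from another probe. The cause of the change with quantile normalization was not tested. The Rb1 ratio was -0.486 with values as deposited, where array medians lie below 0, a move larger than its SD of 0.16. No signal over background was used, so dim spots limit single ratios to an unknown degree.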

Other observations

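The comparison of probes of the same gene was chosen after the gene results were seen. No list of other retinal cell types passed camera. The mean over arrays of the list median minus that of all genes was 0.06 ± 0.17 for amacrine and horizontal cells (adjusted p = 0.948), -0.04 ± 0.31 for ganglion cells (0.916), 0.07 ± 0.17 for Muller glia (0.916) and -0.04 ± 0.21 for retinal progenitors (0.916), each SD with n = 5. Single genes within them had large ratios on arrays 1 and 3. Foxn4, a factor of amacrine and horizontal cell fate, had 2.84, -0.09, 2.99, 0.64 and -0.23 on arrays 1 to 5, and Isl1, a factor of ganglion and bipolar cells, -2.16, -0.10, -1.81, -0.81 and -0.62. Pax6, shared by the amacrine and progenitor lists, had -0.65, -0.51, -0.92, -1.59 and -0.60. None of these genes passed over all genes.

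No list of cell state passed either. The mean over arrays of the list median minus that of all genes was -0.07 ± 0.20 for histones (adjusted p = 0.934), -0.07 ± 0.22 for p53 and apoptosis (0.948), -0.01 ± 0.28 for stress and heat shock (0.803) and 0.05 ± 0.21 for glycolysis and hypoxia (0.803), each SD with n = 5. Cholesterol synthesis gave 0.22 ± 0.26 (SD, n = 5, adjusted p = 0.237) and lay above all genes on 4 of 5 arrays, at 0.54 on array 3 and 0.43 on array 5. Msmo1 of cholesterol synthesis had 1.00, 0.35, 0.63, 1.51 and 0.47 on arrays 1 to 5, Hspa9, a mitochondrial chaperone, 0.51, 0.42, 0.47, 1.25 and 0.49, and Ldha, lactate dehydrogenase, -2.03, -0.01, -1.52, 0.16 and -1.04.

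Probes of the same gene resembled each other little within an array. Over 591 genes with several probes measured on all 5 arrays, the Spearman correlation across genes between 2 of a gene's probes was 0.142, 0.0719, 0.168, 0.17 and 0.101 on arrays 1 to 5. Of 90 combinations of a list and an array, 14 lay in the outer 1% of random lists of the same size, where chance gives 0.9. Genes of a list are not independent, so this count describes these arrays and is no test.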
